A study of Caenorhabditis elegans with 2 samples.

How the data were processed

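The data are transcription factor ChIP-seq peak lists from whole starved L1 Caenorhabditis elegans larvae of strain OP367, with eGFP-tagged LSY-2, from 2 biological replicates per the labels. DNA fragments had a size range of 150 to 350 bp, per the labels, which name LSY-2 as the antibody and eGFP-tagged LSY-2 as the target. Per the deposited README texts, each replicate's list of peaks and background was derived from that replicate's alignments and a control file, a pooled list from both replicates' alignments and a control, and the optimal thresholded list of an irreproducible discovery rate analysis from those 3 lists. Each came in the ce11 and the ce10 build. The aligner, the peak caller and their versions are not given in the sources used here, and neither is the read depth per sample.

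The authors' signal value per region was used as deposited, to describe, rank and filter peaks within a list, and how it was scaled is not stated. The authors' q-value column holds −log10 of q, and it has a ceiling reached by 7696 pooled regions, 6602 of replicate 1 and 8060 of replicate 2. The p-value column of the deposited lists holds a placeholder for every region and was not used. The summit offset per region is the authors' own. All 6850 thresholded peaks were the 6850 strongest regions of the pooled list by signal. A further 846 pooled regions carried the same highest q-value and were not in the thresholded list, and 38 peaks repeated the interval of another peak with a different summit.

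Coordinates are 1-based and in ce11, which is the WBcel235 assembly. Genes came from Ensembl release 115, with 19973 protein-coding genes on the 6 nuclear chromosomes. MicroRNA genes that the annotation named by a miRBase number took the RefSeq symbol of the same span. No coordinates were converted between builds. A gene had a promoter peak when a summit lay from 1000 bp upstream to 200 bp downstream of its 5′ end. To make chance levels, all summits of a chromosome were moved by a common random offset, wrapping at its end, 1000 times.

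The tests, the 31 gene lists and the rule for named genes were fixed before the data were examined. The rule took lsy-2 and unc-119, the ASE laterality list, the genes at the 20 peaks of highest signal, up to 4 members with the strongest promoter peak and up to 2 with none for each other list, and the first 10 words by p on the discovery chromosomes. Lists held 585 names or name prefixes, of which 10 matched no protein-coding gene. 6 of these were microRNA genes and 4 (nsy-5, daf-21, elt-5 and gei-7) had no gene of that name. Lists were tested with Fisher's exact test, two-sided, against all other protein-coding genes, with Benjamini-Hochberg adjustment and a threshold of 0.05. The second test compared each list's share of all genes with a peak with that after the shifts. This statistic replaced a log odds ratio with a continuity correction after results were seen, because the latter gave lists with 0 members the smallest possible p by construction, and fewer lists passed with the replacement. X was compared with the autosomes, and the middle of 3 equal parts of each chromosome with the outer parts, by exact binomial tests. Words of 6 bases, taken with their reverse complements, were counted in windows of 101 bp around summits and in 2 flanks centred 300 bp away, with discovery on chromosomes I, III and V and the test on II, IV and X. Replicate agreement used the 6850 strongest regions of each replicate, since those lists hold background as well.

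The list, shift and word tests were tested on simulated data. With 40 members per list over 19973 genes, all 50 lists with peaks at 60% of members were called against 20% elsewhere, and 1 of 150 unchanged lists was. Members were drawn at random and peaks set gene by gene, so shared promoters and clusters of paralogs were not simulated. The shift test called 1 of 20 uniform peak sets, and 14 of 620 list tests on shifted peaks gave p below the threshold. The uniform sets placed summits independently and used fewer shifts than the main test, so the false calls of the promoter test for clustered summits are unknown. With words of 8 bases, a planted word ranked 1, with 28 words called, and 0 words were called with none planted. The main word test used words of 6 bases, and a GC difference between windows and flanks was not simulated. The false calls of the main word test under such a difference are therefore unknown. Confidence intervals of shares are 95% Wilson intervals and cover counting error only. The p-values from shifts, genes or windows describe this peak list and not the spread between animals.

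Alternatives were another build, other promoter windows (500 bp upstream and 100 bp downstream, 2000 bp and 500 bp), other tolerances and overlaps between replicates, the 3425 stronger peaks alone, each replicate's 6850 strongest regions in place of the thresholded list, the nearest gene only, other backgrounds, flanks at 600 bp and words of 8 bases. Those chosen after seeing the data were the 5′ ends of all 32512 coding transcripts, whole gene spans, words at summits outside promoters, flanks weighted to the GC content of the windows in bins of 5%, and gene types without piRNA genes. Families by name were set against 10000 shifts of their own. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Signal tracks and alignments were not used here.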

Results

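Chromatin immunoprecipitation and sequencing located LSY-2, a C2H2 zinc finger transcription factor with a role in the left-right asymmetry of the ASE gustatory neurons, in whole L1 larvae of Caenorhabditis elegans starved after bleaching. The worms were of strain OP367, an unc-119 mutant that carries the wgIs367 transgene, from which LSY-2 is made with an eGFP tag. There were 2 biological replicates of mixed sex in 1 group, and no second condition, so the comparisons are between peaks and the rest of the genome and between the replicates. The authors' thresholded list, made from both replicates, held 6850 peaks in the ce11 build, and the pooled list and each replicate's list held 30000 regions, background included. Read depth is unknown, so no counting error is given for signal values.

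The strongest LSY-2 peaks lay upstream of genes that included ribosomal protein, cytochrome c oxidase and chaperonin genes. The first by the authors' signal value was at rpl-3, a large ribosomal subunit protein gene, with a signal of 24270. It was followed by a peak of 23603 at rpl-20 and Y17G9B.5, one of 21808 at cox-5A, a cytochrome c oxidase subunit gene, one of 21737 at rpl-15 and K11H12.8, and one of 18382 at ifet-1 and rps-1. All 20 of the strongest peaks had their summit in a promoter window, from 1000 bp upstream to 200 bp downstream of a protein-coding 5′ end, and 6 of them lay at a ribosomal protein gene. Other genes at these 20 peaks included the chaperonin subunits cct-8 and cct-1, the elongation factors eef-1A.1 and eef-2, and the elongation factor homolog elof-1. They also included rps-20 with ekl-4, rpl-11.2, lin-53, which encodes a histone-binding protein, and cbp-1, a histone acetyltransferase gene. Several of these summits were shared, that of cct-8 with Y55F3AR.2, cct-1 with mig-5, eef-2 with clsp-1, eef-1A.1 with rfc-4, elof-1 with lin-7 and lin-53 with nra-2. The summits of cct-8, cct-1, eef-1A.1 and lin-53 lay nearer to the 5′ end of the other gene, and those of eef-2 and elof-1 nearer to their own. The remaining peaks lay at F55A11.1 and syx-5, gmps-1 and cap-2, serp-1.1, cup-14 and ndub-8, T26A8.4 and pdtf-1, and wdr-46. The weakest of the 20 was at cbp-1, with a signal of 10361, and its summit was at −893 bp relative to the 5′ end.

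The rpl-3 peak spanned 3867255 to 3867870 on chromosome III, with its summit at 3867572, or −282 bp relative to the 5′ end of the gene. Its signal was 11843 in replicate 1 and 12487 in replicate 2. The cox-5A peak spanned 12904907 to 12905476 on the same chromosome, with its summit at −301 bp, and had signals of 10711 and 11151 in the replicates. The peak of rpl-20 lay on chromosome IV from 4749791 to 4750324, with signals of 11900 and 11739. Signal across the list had a median of 169, with quartiles of 101 and 343, and 392 peaks had a signal of at least 1000. The peaks had a median width of 376 bp, and 51.3% had exactly that width. Every thresholded peak carried the same −log10 q, 4.19, the highest value in the pooled list, so q did not rank them.

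Neither locus named by the strain had a thresholded peak in its promoter window. lsy-2, on chromosome X from 2089704 to 2093256, had no region of the pooled list there either, and unc-119, on chromosome III, had a pooled region with a signal of 21.4, under the lowest thresholded signal of 68.8. Copies of the locus in the transgene and any removal of regions before the lists were made were not analysed here, so the lack of a listed region at lsy-2 does not show a lack of signal. Of the 30 measured genes of the ASE laterality list, 5 had a promoter peak. They were unc-37, a Groucho corepressor gene, with a signal of 282, lsy-12 with 249.5, lsy-13 with 294, lin-49 with 333 and sox-2 with 269. The list's share of 16.7%, against 21.1% of other genes, did not pass the test (Fisher's exact test, two-sided, adjusted p = 0.73, odds ratio 0.806). cog-1, die-1, che-1, fozi-1 and lim-6 were among the 25 without a thresholded peak. The microRNA gene lsy-6 had none either. Of the 25, die-1, lsy-22, nsy-1 and nsy-4 had a pooled region in the window, with signals of 29.9, 28.9, 17.1 and 45.3, and the others had no such region. Whole larvae were used, so the lists do not resolve binding confined to a few cells.

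The replicates placed the peaks alike. Among the thresholded peaks, 89% had their summit within 100 bp of a summit among the 6850 strongest regions of replicate 1, and 91.0% of replicate 2. Circular shifts of the summits along the chromosomes gave means of 1.45% for each and at most 2.03% and 2.00% (permutation test, one-sided, p = 0.001, the smallest that 1000 shifts can give). Of the 6850 strongest regions of replicate 1, 81.1% had a partner in those of replicate 2, against at most 1.99% of shifted ones (same permutation test, p = 0.001). Between the full replicate lists, background included, this share was 46.5%, against a mean of 6.3% after shifts. The thresholded list derives from the same replicates, so its agreement with each is not independent of them.

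Signal values were compared at the 6616 peaks, 96.6% of the list, that had a region in both replicate lists. Spearman's rho was 0.889 across peaks, which are not independent replicates. The log2 ratio of replicate 2 to replicate 1 had a median of 0.20 and an SD of 0.52 across peaks, so a difference between single peaks of less than 1.43-fold was within 1 SD of the replicate difference. The scatter was smaller at strong peaks, with an SD of 0.20, or 1.15-fold, among the 221 with a signal of at least 1722. The peaks of rpl-3, rpl-20 and rpl-15 differed from each other by less than either value, and each exceeded the signal of lin-53, 12621, by more than both.

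**Figure D1:**
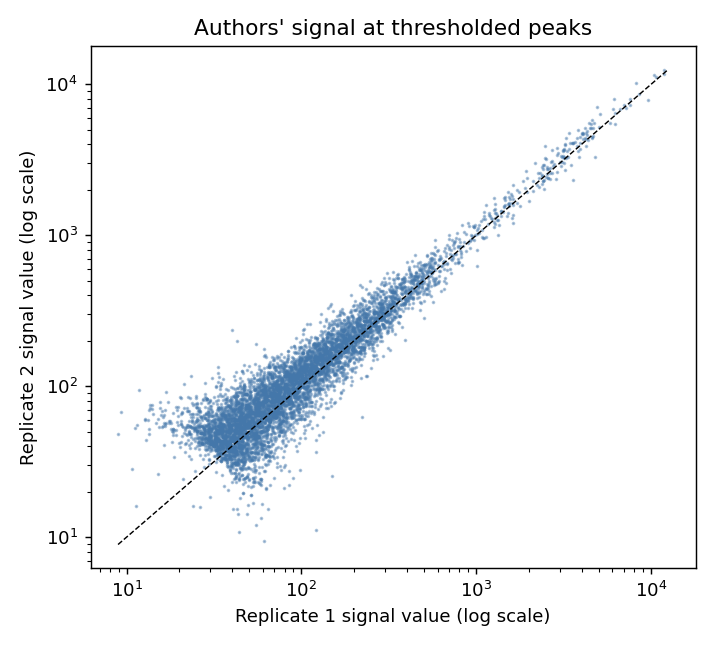
Authors' signal value of replicate 1 (x axis, log scale) and replicate 2 (y axis, log scale) at the 6616 thresholded peaks with a region in both lists, 1 point per peak, with equality as a dashed line. Points follow the line (rho 0.889) and scatter more widely at low signal.

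LSY-2 summits concentrated just upstream of genes and were scarce in coding sequence. In promoter windows of protein-coding genes lay 48.8% of the summits, against a mean of 21.3% after circular shifts (SD 0.543 over shifts) and at most 22.7% (permutation test, two-sided, p = 0.002, the smallest possible). Summits in promoters had a median position of −181.5 bp relative to the nearest 5′ end, where negative is upstream, with quartiles at −346 and −87 bp. With the peaks in 10 equal groups by signal, the share was 29.9% in the weakest group, 42.9% in the fifth and 80.1% in the strongest. Coding sequence held 130 summits, or 1.90%, where shifts gave 24.8% on average. Annotated 5′ UTRs held 3.59% against 1.42%, 3′ UTRs 1.59% against 3.39%, introns 26% against 34.2%, and sequence outside protein-coding genes 66.9% against 36.2%, each with p = 0.002 by the same permutation test. Of the 3510 summits outside promoter windows, 44.9% were in introns and 49.5% outside protein-coding genes.

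**Figure D2:**
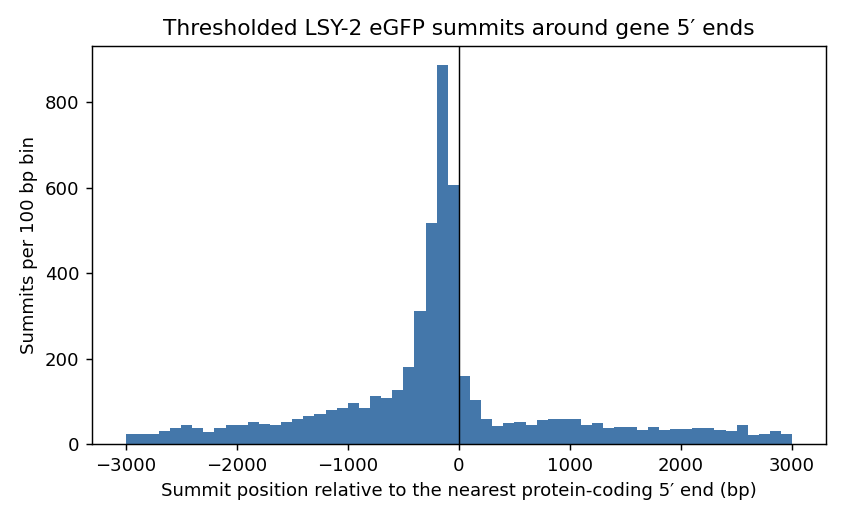
Number of thresholded summits in bins of 100 bp (y axis) by position relative to the nearest protein-coding 5′ end in bp (x axis, negative upstream). The highest bins lie within 500 bp upstream, which held 36.6% of all summits.

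Of 19973 protein-coding genes, 4216, or 21.1%, had a summit in the promoter window, against a mean of 1551 and at most 1729 after shifts (permutation test, two-sided, p = 0.002). Of the 3340 promoter summits, 1015 served more than 1 gene. Of the 31 gene lists chosen before the data were examined, 10 had peaks at a larger share of members than other genes and 10 at a smaller share (Fisher's exact test, two-sided, Benjamini-Hochberg over lists), and 11 passed in neither direction. Genes share promoters and paralogs lie in clusters, so each list was also set against the circular shifts, and 10 of these 20 lists passed that test after adjustment.

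Genes of the basic cell machinery carried LSY-2 peaks most often. Ribosomal protein genes had a promoter peak in 74 of 81 cases, or 91.4%, against 20.8% of other genes (odds ratio 37.8, adjusted exact p = 6.6e-41), with a median signal of 1947 at those with a peak. rpl-3, rpl-20, rpl-15 and rps-1 were the strongest, and rps-16 and rpl-27 were among the 7 with none. Proteasome genes had peaks in 29 of 33, led by rpn-5 (signal 9111) and pas-4 (8924), with none at pbs-5 and rpt-4 (odds ratio 24.7, adjusted exact p = 4.1e-15). Genes of the mitochondrial respiratory chain had peaks in 25 of 29, led by cox-5A and atp-1 (10197), with none at nuo-4 and nuo-5 (odds ratio 21.3, adjusted exact p = 6.1e-13). Genes of splicing and RNA polymerase II had peaks in 39 of 54, led by snr-6 (9051) and rpb-3 (8924), with none at rpb-2 and rpb-9 (odds ratio 9.60, adjusted exact p = 8.6e-15). The peak of pas-4 and rpb-3 is one and the same. All 4 lists also passed against shifts (permutation test, adjusted p = 0.0077), and both replicates gave the same direction. With each summit given to the nearest 5′ end alone, the shares were 53.1%, 57.6%, 62.1% and 48.1% in that order, with odds ratios of 6.02, 7.12, 8.52 and 4.93. There body wall muscle genes, at 57.9%, were above all of these but the respiratory chain, so the ranking of lists depends on how summits are given to genes. Against genes with a pooled region in the window the odds ratios were 7.93, 9.34, 13.4 and 6.96, and all 4 calls were kept under both alternatives, while the longer window of 2000 bp upstream and 500 bp downstream gave 61.2 for ribosomal protein genes.

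Cell cycle, chromatin and muscle genes followed. Cell cycle and replication genes had peaks in 25 of 41, with orc-1, an origin recognition subunit gene, at a signal of 7133 and mcm-4 at 1577, and none at cdk-2 and cyb-2.1 (odds ratio 5.80, adjusted exact p = 1.2e-07). The synMuv and chromatin repressor list had peaks in 22 of 35, with lin-53 at 12621, lin-9 at 9637 and lin-54 at 2527, and none at lin-37 and lin-15A (odds ratio 6.26, adjusted exact p = 3.3e-07). Its call was lost when only genes with any pooled region in the window served as background (odds ratio 2.73, adjusted exact p = 0.058). Body wall muscle genes had peaks in 24 of 38, with the myogenic factor gene hlh-1 at 912, unc-112 at 463 and unc-45 at 441, and none at unc-22 and tni-3 (odds ratio 6.34, adjusted exact p = 9.4e-08). Their median signal was 142, and the call was lost among the 3425 stronger peaks (odds ratio 2.16, adjusted exact p = 0.078). With the nearest 5′ end alone, the odds ratios of these 3 lists were 3.78, 4.0 and 7.23, in the order given. Against genes with a pooled region, those of cell cycle and body wall muscle genes were 3.66 and 4.30 (adjusted exact p = 0.0080 and 0.0062). These calls were kept. Against shifts, these 3 lists passed with adjusted p = 0.014, 0.019 and 0.0077 (permutation test).

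Regulatory and neuronal lists had smaller odds ratios in the main test, and differences between lists were not tested. The heterochronic list, genes that time larval development, had peaks in 8 of 15, led by nhl-2 (1995) and lin-46 (738), with lin-28 at 397 and none at lin-41 and lin-42 (odds ratio 4.24, adjusted exact p = 0.010). The pan-neuronal list had 12 of 26, led by tbb-1 (473) and ric-19 (462), with none at unc-64 and ric-4 (odds ratio 3.23, adjusted exact p = 0.010). The insulin, dauer and starvation list had 19 of 45, led by ire-1 (8912), an endoplasmic reticulum stress sensor gene, and the autophagy gene lgg-2 (1093), with none at age-1 and pdk-1 (odds ratio 2.76, adjusted exact p = 0.0029). The first and the third lost their call with the shorter window of 500 bp upstream and 100 bp downstream (adjusted exact p = 0.38 and 0.12), and the pan-neuronal list among the stronger peaks (0.068). All 3 lost it against genes with a pooled region in the window, with odds ratios of 4.46 for the heterochronic, 0.786 for the pan-neuronal and 1.33 for the insulin, dauer and starvation list (adjusted exact p = 0.18, 0.84 and 0.67). With the longer window the odds ratios were 6.89, 5.87 and 4.83, where that of the synMuv and chromatin repressor list was 5.07. Over whole gene spans, chosen after seeing the data, those of the heterochronic, pan-neuronal and insulin, dauer and starvation lists were 15.7, 4.57 and 4.75. None of these 3 passed against shifts (permutation test, adjusted p = 0.32, 0.24 and 0.16).

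Chemoreceptor genes were almost without LSY-2 peaks. Of 1309 of these G protein-coupled receptor genes, 17, or 1.3%, had a promoter peak, against 22.5% of other genes (odds ratio 0.0466, adjusted exact p = 8.1e-110), and srh-16 was highest at 919. C-type lectin genes had 8 of 240, led by clec-53 at 452 (odds ratio 0.135, adjusted exact p = 1.1e-14) and F-box genes 26 of 322, led by fbxc-23 at 5165 (odds ratio 0.330, adjusted p = 1.0e-09). These 3 passed against shifts (permutation test, adjusted p = 0.0077). A background limited to genes with a pooled region in the window leaves out genes with no region at all, and held 55 chemoreceptor genes. Of these, 17, or 30.9%, had a peak against 56.2% of other genes. In that background the call was kept, with an odds ratio of 0.355 (adjusted exact p = 0.00085), weaker than the 0.0466 above. There the F-box odds ratio was 1.55 and the lectin odds ratio 0.703, and neither passed (adjusted exact p = 0.36 and 0.67).

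The other 7 lists with a smaller share passed by Fisher's exact test but not against shifts. Detoxification genes had peaks in 16 of 185 (adjusted exact p = 2.0e-05), collagen genes in 16 of 174, led by col-38 at 5900 (8.9e-05), neuropeptide genes in 6 of 102, led by nlp-4 at 4359 (0.00010), major sperm protein genes in 0 of 31 (0.0029), and insulin-like peptide genes in 1 of 39, ins-39 at 620 (0.0047). Histone genes had 7 of 72, led by his-37 at 1614 (0.032), and intestine genes 2 of 36, erm-1 at 267 and elt-2 at 85.4 (0.034). Against shifts, their adjusted p ran from 0.077 to 0.69 (permutation test). The histone and intestine calls were also lost with either replicate alone, at adjusted exact p = 0.35 and 0.51 without replicate 2 and 0.12 and 0.10 without replicate 1. Both were lost with the nearest 5′ end alone (adjusted exact p = 0.057 and 0.16). That of histones was lost with the shorter window (adjusted exact p = 0.22), and that of intestine genes with the longer window (0.057) and among the stronger peaks (0.073). Histone odds ratios were 0.427 in the main test, 0.428 with the nearest 5′ end and 0.574 with the shorter window. For intestine genes they were 0.270 in the main test, 0.381 with the nearest 5′ end, 0.372 with the longer window and 0.247 among the stronger peaks. The calls of collagen and detoxification genes were lost against genes with a pooled region in the window (adjusted exact p = 0.47 and 0.093), as was that of histone genes, whose direction turned (odds ratio 1.31, 0.91), and that of insulin-like peptides among the stronger peaks (0.060). Intestine genes kept their call against genes with a pooled region, with 2 of 22 and an odds ratio of 0.0954 (adjusted exact p = 4.6e-05).

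Lists that passed in neither direction covered most tissues and factor families. They included heat shock genes with 9 of 27, led by hsp-60 (2309), and Wnt pathway genes with 8 of 28. The latter were led by mig-5 (14134), at the summit it shares with cct-1. Epidermis and seam genes had 8 of 31, led by nhr-23 (216), and bHLH factors 8 of 38, led by hlh-1. Homeobox genes had 18 of 98, led by ceh-38 (2698), germline and P granule genes 9 of 49, led by gld-3 (2058), nuclear hormone receptors 48 of 269, led by nhr-142 (666), ciliated neuron genes 6 of 34, led by dyf-3 (1842), pharynx genes 4 of 36, led by eya-1 (199), and vitellogenins 0 of 6. Heat shock genes passed as higher without replicate 1 (odds ratio 2.59, adjusted exact p = 0.030) and among the 3425 stronger peaks (odds ratio 3.01, adjusted exact p = 0.024), and nuclear hormone receptors as lower among those peaks (odds ratio 0.426, adjusted exact p = 0.00019). Over whole gene spans, an alternative chosen after seeing the data, the Wnt pathway and epidermis lists passed as higher (adjusted exact p = 0.025 and 0.031).

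**Figure D3:**
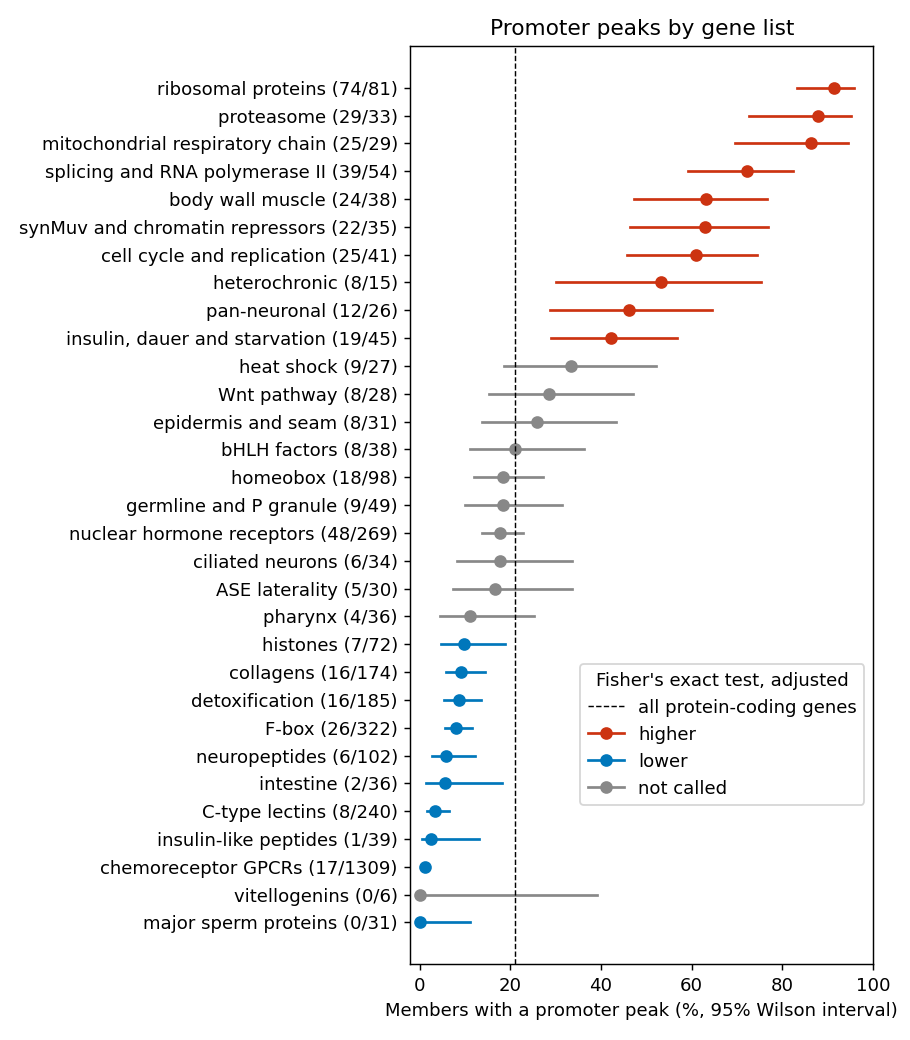
Percent of each list's members with a promoter peak (x axis) for the 31 gene lists (y axis, members with a peak and members in parentheses), with 95% Wilson intervals that cover counting error only and the 21.1% of all protein-coding genes as a dashed line (red, higher and blue, lower by Fisher's exact test, grey, neither). Ribosomal protein, proteasome and respiratory chain genes lie above 86%, and chemoreceptor genes at 1.3%.

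Small noncoding RNA genes differed by type. Among all 46890 annotated nuclear genes, tRNA genes had a summit in the window in 245 of 612 cases, or 40%, and snoRNA genes in 152 of 346, or 43.9%, against 13.8% and 13.9% of genes of other types (Fisher's exact test, two-sided, Benjamini-Hochberg over gene types, adjusted p = 4.2e-56 and 5.9e-41). Of 15363 piRNA genes 492, or 3.20%, had one (odds ratio 0.137), and of 2128 pseudogenes 76, or 3.57% (adjusted exact p = 3.0e-61). The many piRNA genes lowered the share of other types, and without them, an alternative chosen after seeing the data, it was 19.1% beside tRNA and 19.2% beside snoRNA genes (adjusted exact p = 1.4e-31 and 8.7e-25). MicroRNA genes had a summit in 59 of 261 cases, or 22.6%, against 14.1% of all other types (adjusted exact p = 0.00037) but 19.5% without piRNA genes, where the call was lost (adjusted exact p = 0.26). None of lin-4, let-7, mir-48, mir-84 and mir-241 had one. Of genes whose own 5′ end lay outside coding promoter windows, 198 of 499 tRNA genes (39.7%) and 88 of 248 snoRNA genes (35.5%) had a summit. No share of other gene types was computed for that subset. Gene types were not set against circular shifts, and neighbouring genes that share a summit were counted apart, so their p-values may be too small.

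Chromosome III had the most peaks, 1334 or 505 per 1000 protein-coding genes, and chromosome V the fewest, 988 or 198 per 1000. Chromosome I had 1309, II 1128, IV 1063 and X 1028. The share of peaks on X was 1.10 times its share of protein-coding genes (exact binomial test, two-sided, p = 0.0015). The direction turned for the 3425 stronger peaks, at 0.916 (exact binomial test, p = 0.052), and relative to chromosome length, at 0.849 (p = 4.1e-09). With each chromosome divided into 3 equal parts, the middle parts held 1.13 times the share of peaks that their share of genes gives (exact binomial test, two-sided, p = 5.3e-17). Chromosome V had 48.9% of its peaks there against 36% of its genes, while chromosome IV had 40.5% against 40.6% and X 33.4% against 35.7%. These exact binomial tests take peaks as independent, which neighbouring peaks may not be, so their p-values may be too small.

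**Figure D4:**
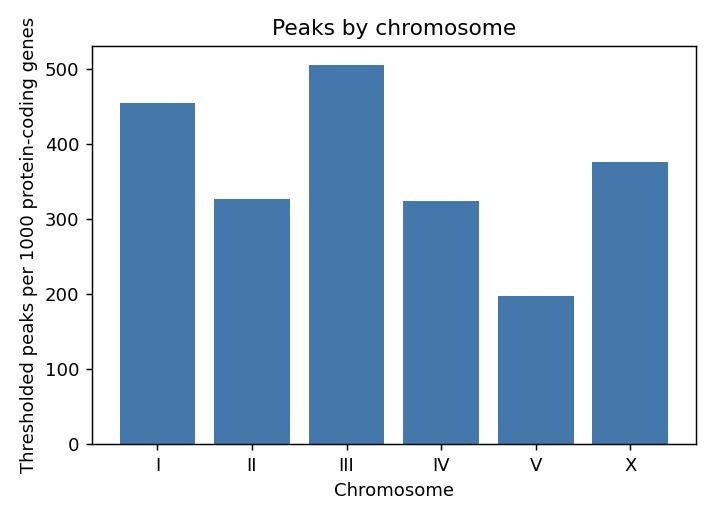
Thresholded peaks per 1000 protein-coding genes (y axis) on each nuclear chromosome (x axis), 1 bar per chromosome. Chromosome III is highest at 505 and chromosome V lowest at 198.

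GA repeats and a GACGCAG-like sequence marked the summits. On chromosomes I, III and V, the word GAGAGA or its reverse complement was within 50 bp of 29.0% of summits and in 6.32% of flanks 300 bp away, and on chromosomes II, IV and X in 27.1% against 5.90%. ACGCAG was in 14.5% of windows and 1.76% of flanks on the latter chromosomes, and GACGCA in 13.8% and 1.93%. The other words among the first 10 by p were AGAGAG, AGAGAC, CGTCTC, AGACGC, CGCAGA and AGAGAA, each more frequent at summits by 2.53 to 5.35 times on chromosomes II, IV and X, and AAAATT, which was less frequent at 18.4% against 43.2%. All 10 passed on both sets of chromosomes (Fisher's exact test, two-sided, Benjamini-Hochberg over 2080 words), with adjusted p of at most 1.2e-80 on the second set. In all, 749 words were more frequent at summits on the first set and 674 of these also on the second. GC content was 44.0% ± 7.69 (SD across windows) at summits and 35.1% ± 8.38 in flanks. With flanks weighted to the GC content of the windows, chosen after seeing the data, 222 of the 674 words stayed more frequent at summits on II, IV and X. The ratio of shares fell from 4.59 to 2.72 for GAGAGA, from 8.22 to 4.05 for ACGCAG and from 7.16 to 4.26 for GACGCA, and AAAATT moved from 0.427 to 0.804.

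Among words of 8 bases, AGACGCAG led, in 10.4% of windows and 0.454% of flanks on chromosomes I, III and V and in 9.07% and 0.513% on II, IV and X (adjusted exact p = 1.3e-138 on the first set). On the second set the ratio of these shares, 17.5, fell to 6.96 with flanks weighted to the GC content of the windows. On II, IV and X its share was 3.32% in the weakest of the 10 signal groups (95% Wilson interval 1.87 to 5.85) and 11.5% in the strongest (8.37 to 15.7). It was 10.2% for promoter summits and 8.09% for the rest. At ribosomal protein genes AGACGCAG was seen at 2 of 71 peaks, or 2.82% (0.776 to 9.70, all chromosomes).

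**Figure D5:**
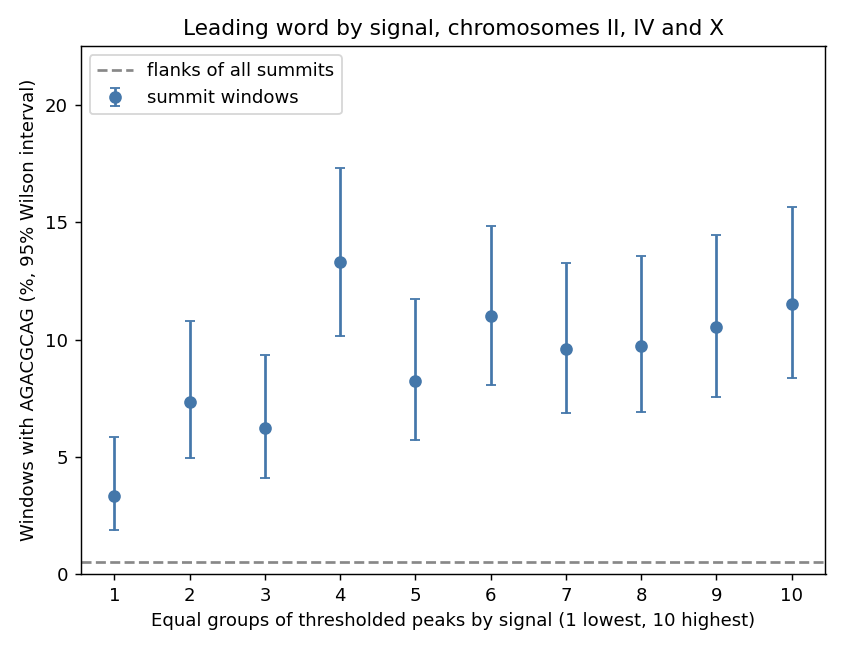
Percent of summit windows of 101 bp with AGACGCAG or its reverse complement on chromosomes II, IV and X (y axis, bars are 95% Wilson intervals that cover counting error only) in 10 equal groups of the thresholded peaks by signal (x axis, 10 the strongest), with the share in flanks as a dashed line. All groups lie above the flanks' 0.513%, from 3.32% to 13.3%.

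The list in the ce10 build held 6853 peaks, with a median width of 376 bp and a median signal of 170. For 6795 of them the ce11 list had a peak of the same chromosome, width, summit offset and signal to 3 digits.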

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

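The promoter share, the replicate agreement and the excess in the middle parts of chromosomes kept their direction and call under each alternative run for them, with promoter shares from 39.1% with the shorter window to 63.5% with all gene types, and the number of genes with a promoter peak ran from 2917 to 5413. Tests on all coding transcripts, whole gene spans, summits outside promoters, flanks weighted to GC content and gene types without piRNA genes were chosen after seeing the data. With weighted flanks 222 words were called in place of 674, all of which the same ratio test called without weights. The 445 words called neither way with weights had a median ratio of 1.83 before weighting and 1.08 after. Of these, 6 had a weighted ratio at or above the unweighted one, and the 95% interval of 55 reached it. This argues against a loss of precision alone for these words as a set, but not for each single word. Without piRNA genes, the odds ratio of ncRNA genes turned from 1.3 to 0.805. Using the 3425 stronger peaks alone changed the peak number to 3425 by construction. The X to gene ratio of 1.10 fell to 0.916 with those peaks and to 0.849 relative to chromosome length. The cause was not tested, and without a replicate the ratio was 1.07 to 1.11. With the background limited to genes with a pooled region in the window, 6 lists were higher and 4 lower in place of 10 and 10, the odds ratio of histones became 1.31, of pan-neuronal genes 0.786 and of F-box genes 1.55, and the cause was not tested. Under the other alternatives 8 to 12 lists were higher and 8 or 9 lower. Major sperm protein genes had no member in that background and so no value there, and kept their call elsewhere. Of the 20 called lists, 7 kept direction and call under all 8 alternatives: ribosomal proteins, proteasome, respiratory chain, splicing and RNA polymerase II, cell cycle and replication, chemoreceptors and neuropeptides. The circular shifts are not among these alternatives, and against them neuropeptides did not pass (permutation test, adjusted p = 0.086), while the rest of these lists did. Words of 8 bases gave 1660 called in both sets of chromosomes against 674 of 6 bases, from 32878 words tested in place of 2080. The count of peaks without a replicate is 6850 by construction. Agreement of thresholded peaks with only the 3425 strongest regions of replicate 1 was 49.4%, since that list is shorter than the thresholded one. Unknown depth leaves the precision of single signal values open.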

Other observations

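The tests on summits inside genes of the 3 lists, on families by name, on genes with many summits, on the strongest peaks by signal, on GC content for words of 6 bases and on the lsy-2 neighbourhood were chosen only after results were seen. Among 117 families of at least 15 genes with a common name, 79 lay mostly outside the fixed lists, and of these 16 had peaks more often than the 21.1% of all protein-coding genes and 14 less often (Fisher's exact test, two-sided, Benjamini-Hochberg over families). None of these 30 families passed against 10000 circular shifts after adjustment, so chance was not excluded for them. Nuclear pore genes (npp) had peaks in 21 of 26 (adjusted exact p = 2.2e-09), translation initiation factor genes (eif) in 20 of 25 (7.6e-09), mitochondrial ribosomal protein genes in 25 of 41 (mrpl, 4.0e-07) and 18 of 29 (mrps, 1.5e-05), vesicle sorting genes (vps) in 19 of 31 (1.1e-05), and vacuolar ATPase genes (vha) in 12 of 20 (0.00073). None of the 56 ligand-gated channel genes (lgc), 56 irld genes or 37 astacin protease genes (nas) had one (adjusted exact p = 2.0e-05, 2.0e-05 and 0.0011). Against shifts, the adjusted p was 0.060 for npp, 0.055 for eif, 0.11 for mrpl, 0.16 for mrps, 0.14 for vps, 0.19 for vha, 0.18 for lgc, 0.23 for irld and 0.39 for nas (permutation test, two-sided, Benjamini-Hochberg over families).

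The 221 peaks with a signal of at least 1722, a value chosen after seeing the data, were set beside the other 6629, with no test of the differences. They lay in promoter windows in 90.5% of cases against 47.4%, and 60.5% of those in promoters served more than 1 gene against 28.5%. GAGAGA was in 14% of their windows against 28.6%, and AGACGCAG in 7.24% against 9.85%. Of the 74 ribosomal protein genes with a peak, 38 had one of these. So did 5 of the 29 proteasome genes with a peak, 5 of the 25 respiratory chain genes and 0 of the 24 body wall muscle genes. The SD of the log2 replicate difference was 0.20 for them and 0.52 for the others.

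For the concentration of peaks at ribosomal protein, proteasome and respiratory chain genes, signal over transcribed gene bodies was not decided. Summits were counted from 1000 bp upstream to the 3′ end of all 143 genes of these lists. Of these summits, 21 of 139, or 15.1% (95% interval 10.1 to 22), lay inside a protein-coding gene. Such genes made up 81.8% of that length. The summits include the promoter peaks that make up the pattern, however, and the promoter window lies mostly upstream. A low share inside genes was therefore largely set in advance. For ribosomal protein genes, promoter crowding is argued against by an odds ratio of 4.37 (95% interval 2.85 to 6.71) with each peak counted once and divergent genes apart. With gene length as well it was 6.66. Crowding was not examined for proteasome and respiratory chain genes. Occupancy without sequence preference may still account for the concentration of peaks at the 3 lists. AGACGCAG was in 11.5% of windows of the strongest of the 10 signal groups on chromosomes II, IV and X (8.37 to 15.7) against 0.169% of their flanks. It was, however, in 5 of the 124 peaks of these 3 lists (4.03%, 1.73 to 9.09) and 0 of their 248 flanks. The bound set before the result was seen used that wider group, which dilutes these genes, and a few peaks with the word exclude nothing for the rest. Peaks of other factors and an untagged control were not analysed here, so binding that any factor would show at such promoters stays open, and no biological explanation was tested.

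The words at summits were weighed against base composition, since GC content was higher there. With flanks weighted to the GC content of the windows, the ratio of shares on chromosomes II, IV and X fell from 17.5 to 6.96 for AGACGCAG (95% interval 4.56 to 10.6) and from 4.59 to 2.72 for GAGAGA (2.37 to 3.14), which argues against GC content as the whole source of either. Of the 674 words of 6 bases, 222 stayed more frequent, 7 became less frequent and 445 passed in neither direction, with a median ratio of 1.83 before weighting and 1.08 after. Of these 445, 6 had a weighted ratio at or above the unweighted one and the 95% interval of 55 reached it, so the part of GC content in single words stays open. Whether LSY-2 itself reads this sequence, or a factor bound beside it does, was not tested.

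The scarcity of peaks at chemoreceptor genes was weighed against their position, since many lie on chromosome arms. Stratified by chromosome and 3 equal parts of its length, the odds ratio was 0.0624 (95% interval 0.0385 to 0.101), which argues against position at this scale. Expression in larvae and chromatin state were not analysed here and stay open.

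A stretch of 63.5 kb around lsy-2, between summits at 2051937 and 2115398 on chromosome X, held no region of the pooled or replicate lists. Of the 13491 gaps between neighbouring summits of these 3 lists on X, 7 were at least as long, this one included, and the median gap was 157 bp. Of 3536 overlapping windows along X that reached 20 kb to each side, however, 4.81% held as few pooled regions as the 0 at lsy-2, against a median of 9. Copies of the locus in the transgene and removal of regions before the lists were made were not analysed here, and no explanation was tested.

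There were 55 genes with at least 5 summits in their span, led by pqn-41 with 16 and fkh-7 with 11, against a mean of 51.7 and at most 72 after shifts (permutation test, two-sided, p = 0.67). Among them, fkh-7 and M01H9.3 (7 summits) exceeded the highest of their shifts, 8 and 6, while pqn-41 did not, at 20. Shifts set against each other gave a mean of 2.64 and at most 8 such genes (permutation test, two-sided, p = 1), so these 2 are not more than chance gave.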
